A study of Rattus norvegicus with 8 samples.

How the data were processed

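MicroRNAs of the renal cortex of male rats were measured with 8 one-colour Agilent arrays, 2 in each of the groups SHAM, UNX, DOCA and DOCA-EVs. Each array received 100 ng of labelled RNA. Per the file headers, the authors scanned 1 slide of design 070154 with Agilent Feature Extraction 11.5.1.1 and protocol miRNA_1105_Oct12. The deposited scanner files give a processed signal per spot as an intensity, background-subtracted and detrended by the software and not normalized between arrays. The deposited series table holds the same intensity, with a largest difference of 0 from the scanner files. Per the file headers, the raw spot and background signals and the software's total signal per miRNA are also intensity values, and the other columns used are flags of 0 or 1 for detection, saturation and outlying spots.

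Each array held 12128 spots of rat miRNAs, 281 positive control spots and 434 negative control spots. The 1806 miRNA probes covered 758 miRNAs, of which 594 had 2 probes, 132 had 4, 29 had 3 and 3 had 1. Spots with outlier flags were left out and the processed signal of the others was averaged per probe. The signal was divided by the 75th percentile of the array over the 271 probes detected on all arrays, with the factors divided by their geometric mean. Probe values under 2.59, the mean standard deviation of the negative controls, were set to 2.59, and the probes of a miRNA were summed before taking log2. A miRNA entered the fit when the software called it detected on every array of at least 1 group, which kept 242 miRNAs (31.9%), 192 of them detected on all 8 arrays. The 516 others were left out. Gene positions are not given, since the assembly named in the file headers differs from that of the reference table.

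Differences were tested with limma 3.58.1 in R 4.3.3, with 1 mean per group, 4 residual degrees of freedom and 2.18 prior degrees of freedom. The tests were two-sided, with Benjamini-Hochberg adjustment over the 242 miRNAs and a threshold of 0.05 on the adjusted p. The main comparisons were UNX against SHAM, DOCA against UNX and DOCA-EVs against DOCA. The secondary ones were DOCA against SHAM, DOCA-EVs against UNX, DOCA-EVs against SHAM, and the pooled comparison of both DOCA-salt groups with both standard-diet groups. An exact permutation test of 2 arrays against 2 cannot give a p below 0.333, so none was used for single miRNAs. Comparisons that share a group are not independent of each other.

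The following choices were made before the data were examined: the comparisons, the miRNA lists, the other settings to be tried, except those named below as added and the rule for naming miRNAs. For a main comparison the rule names up to 12 miRNAs per direction with the smallest p among those past the threshold, filled to 6 per direction with others. For a secondary comparison it names up to 5 per direction among those past the threshold. It also names 2 to 4 members of each list, and miR-21-5p, miR-192-5p, miR-200b-3p, miR-29b-3p, miR-142-3p and miR-451-5p whatever their p. The 16 lists were fibrosis-associated miRNAs, the miR-29, miR-200, miR-30 and let-7 families, kidney tubule-enriched, leukocyte, erythrocyte, endothelium and smooth muscle, striated muscle, and liver, nerve and endocrine miRNAs, the miR-17 cluster and its paralogues, mesenchymal stromal EV cargo, mineralocorticoid and sodium transport, hypoxia and p53, and the imprinted Dlk1-Dio3 cluster. Some miRNAs are in more than 1 list. Lists with at least 3 members in the fit were tested with camera of limma at an inter-gene correlation of 0.01, which applied to 14 lists. The same test with an estimated correlation and fry of limma were alternatives. No list call held with the estimated correlation, whereas fry, which tests a list by itself and not against other miRNAs, called 5 lists in DOCA against UNX, 4 in the pooled comparison and 0 in both other main comparisons. Calls of list members were counted over all 242 miRNAs and adjusted over the list alone.

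A miRNA was taken as above background on an array when at least 1 of its probes was well above background on at least 0.5 of its spots. Where no array of 1 group met this, the fold is given as a bound: the level of such a group was replaced on each array by the level of the dimmest miRNA above background, or by its own level where that was higher. Where some arrays of the lower group met this and others did not, the others were replaced in the same way for miRNAs past the threshold. No fold is given where neither group met it. The bounds refer to the main scaling.

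The replicate numbers equal the 2 rows of the slide and the groups equal its 4 columns. Deviations from the group mean correlated across miRNAs between arrays of the same number in all 6 pairs of groups, with r from 0.245 to 0.557; miRNAs are not independent replicates. The values with the replicate number as a block, and the values within each slide row (1 array per group), are therefore given beside the results.

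The fit was tested on simulated data with 40 of 242 miRNAs changed in each of 20 runs. For 2 arrays against 2 it recovered 17.5% of changes of 0.5 log2, 71.2% of changes of 1 and 95% of changes of 2, with 3.80% of calls false. For 4 against 4 it recovered 48.2%, 88.5% and 98.8%, with 4.45% of calls false. Lists without a change were tested as UNX against SHAM in both sets of runs, and 3 of 280 and 2 of 280 were called. The simulated miRNAs varied independently of each other, each with the same spread on all arrays. On the measured arrays the estimated correlation within the tested lists ran from −0.04 to 0.87. The runs therefore cannot show how often correlated lists are called falsely. The measured groups also differed in spread, with a median replicate difference of 0.06 log2 in SHAM and 0.37 in DOCA-EVs. The recovery and the share of false calls under such unequal spread were not simulated.

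The alternatives were 5 other scalings, 3 other probe summaries, the deposited table, 2 other filters, a floor 4 times lower or higher, a variance trend, robust variance, array weights, the compared groups alone, the replicate block, and leaving out each array in turn. Of the other scalings, normexp and quantile normalization also corrects the background anew and adds an offset of 50 to each signal. The offset draws fold changes of dim miRNAs towards 0. Added after seeing the data were a fit without the 2 arrays with weak hybridisation controls and a fit with outlier spots kept. The scaling moved the median log2 fold change of all miRNAs by over 0.1. For UNX against SHAM it was −0.12, and ranged up to 0.19 with no scaling. For DOCA against UNX it was 0.08, −0.18 with the median of the probes detected on all arrays and −0.50 with no scaling. For DOCA-EVs against DOCA it was 0.00, 0.14 with the median and 0.44 with no scaling. For the pooled comparison it was −0.01, −0.17 with the median and −0.20 with no scaling. List medians are therefore also given relative to the median of all miRNAs.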

Results

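MicroRNA levels were measured in the renal cortex of male rats on 8 arrays, 2 in each of 4 groups. UNX rats had undergone nephrectomy and received a diet with 0.50% sodium, and SHAM rats were sham-operated on the same diet. DOCA rats had undergone nephrectomy and received 1.5% sodium with deoxycorticosterone acetate, a mineralocorticoid, at 8 mg/kg 2 times a week. DOCA-EVs rats received the same and, from week 2, weekly intravenous extracellular vesicles of adipose mesenchymal cells. The labels do not state that the replicates are separate rats, so the p-values refer to the spread between arrays. Of the 758 rat miRNAs on an array, 208 on DOCA replicate 2 to 264 on DOCA-EVs replicate 1 were detected, and 242 entered the comparisons. The median absolute difference between replicates was 0.06 log2 in SHAM, 0.18 in UNX, 0.25 in DOCA and 0.37 in DOCA-EVs. The fit assumes an equal spread in all groups and shares it between them. The p-values of every comparison therefore draw also on the small spread of SHAM. The hybridisation control dmr_3 gave a signal of 1028 on DOCA replicate 2 and 1136 on DOCA-EVs replicate 2, against 2200 to 2402 on the 6 other arrays. These 2 arrays are called weakly hybridised below after such controls alone. The 75th percentile of the probes detected on all arrays was low only on DOCA replicate 2, at 282. It was 451 on DOCA-EVs replicate 2 and 395 to 519 on the 6 others. The number of arrays limits the precision: the median 95% confidence interval reached 0.47 log2 to either side for 2 arrays against 2 and 0.33 for 4 against 4. Levels below are log2 normalized signal as mean ± SD with n = 2 unless stated, and log2 fold changes are given ± SE. The slide column follows the group, so the column and the group cannot be told apart.

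UNX against SHAM addresses the effect of nephrectomy under standard sodium. No miRNA passed the threshold. The values with the smallest p were those of miR-494-3p, at 9.20 ± 0.16 in UNX and 10.03 ± 0.11 in SHAM (log2 fold change −0.84 ± 0.18, adjusted p = 0.36), and miR-96-5p, at 6.14 ± 0.26 and 5.42 ± 0.07 (0.72 ± 0.17, adjusted p = 0.36). Among miRNAs with a negative value were miR-1224 (−0.51 ± 0.15) and miR-145-5p of smooth muscle (−0.47 ± 0.14). miR-375-3p, a miRNA of endocrine cells, was measured at least 1.19-fold lower, and miR-770-3p and miR-188-5p were not above background in either group. Positive values belonged to miR-10a-5p (0.27 ± 0.12) and miR-10b-5p (0.26 ± 0.12), both enriched in kidney epithelium, to miR-146a-5p (0.26 ± 0.12), which acts in innate immune signalling, and to miR-200b-3p (0.23 ± 0.12), while miR-128-3p was measured at least 1.28-fold higher. limma gave 0 miRNAs past the threshold, and 16 of 242 at an unadjusted p under 0.05 (2 higher and 14 lower), where chance gives 12.1. With array weights 3 miRNAs passed, all lower in UNX: miR-375-3p, miR-494-3p and miR-770-3p. The replicate block also gave 0.

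The let-7 family, linked to differentiation, was the 1 list of 14 that passed in UNX against SHAM. All 8 measured members had a positive value and none passed alone, with let-7f-5p at 0.21 ± 0.12 and let-7a-5p at 0.14 ± 0.13. The list lay 0.26 above the median of all miRNAs (0.08 to 0.27 over the 6 scalings) with camera adjusted p = 0.029, and adjusted p = 0.78 with an estimated correlation. It lay 0.16 and 0.29 above that median in slide rows 1 and 2, and the adjusted p with the replicate block was 0.026. The call was lost with quantile normalization (adjusted p = 0.42), with miRNAs detected on all 8 arrays alone (0.053) and without UNX replicate 2 (0.18), where the list median was 0.08 instead of 0.14. It was 0.21 without both arrays with weak hybridisation controls. The 13 other lists had camera adjusted p from 0.074 for the mesenchymal stromal EV cargo, at a median log2 fold change of 0.14, to 0.86 for fibrosis-associated miRNAs, at −0.18.

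DOCA against UNX addresses the effect of mineralocorticoid and high sodium after nephrectomy. miR-155-5p, an inflammatory miRNA of activated leukocytes, rose at least 2.15-fold in DOCA, from 3.90 ± 0.09 to 5.28 ± 0.04 (log2 fold change 1.38 ± 0.16, adjusted p = 0.018), being above background on 1 of the 2 UNX arrays. miR-188-5p rose at least 2.18-fold (adjusted p = 0.018). miR-132-3p, a CREB-regulated miRNA, rose at least 1.36-fold (adjusted p = 0.018); it was above background on 1 of the 2 DOCA arrays and on no UNX array. miR-375-3p also passed, with a lower level in DOCA (adjusted p = 0.033), but it was not above background on any of the 4 arrays, so no fold is given. The folds and bounds hold for the main scaling. Over the 6 scalings the values ran from 0.16 to 1.38 for miR-155-5p, 0.15 to 1.13 for miR-188-5p and 0.17 to 2.02 for miR-132-3p, each nearest 0 with normexp and quantile normalization. All 4 lay on the same side in both slide rows, which carries no weight for miR-375-3p below background. The rows gave 1.41 and 1.35 for miR-155-5p, 1 of them against a UNX array where it was not above background. Values that did not pass included miR-34a-5p, a p53 target (0.64 ± 0.12, adjusted p = 0.051), miR-21-3p (at least 2.45-fold higher, 0.051) and miR-146b-5p, induced by NF-κB (at least 4.22-fold higher, 0.051). Among those with a negative value were miR-192-5p (−0.65 ± 0.14, adjusted p = 0.063), miR-30e-3p (−0.54 ± 0.12, 0.073) and miR-10a-5p (−0.47 ± 0.12, 0.085). For miR-192-3p the measured bound was at least 1.05-fold lower, and miR-9a-5p was not above background in either group. miR-21-5p, a miRNA linked to kidney fibrosis, was 12.19 ± 0.07 in DOCA and 11.10 ± 0.10 in UNX (1.08 ± 0.34, adjusted p = 0.12).

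In DOCA against UNX limma gave 4 miRNAs past the threshold, 3 higher and 1 lower, and 56 at an unadjusted p under 0.05. The split of higher and lower miRNAs was 2 and 1 with all probes in the scaling, 0 and 1 with quantile normalization, 5 and 15 with the median of detected probes, and 0 and 10 with normexp and quantile normalization. With no scaling it was 0 and 0. The replicate block gave 5 calls, the fifth being miR-146b-5p (adjusted p = 0.027). No miRNA passed without either replicate of SHAM, UNX or DOCA, whereas more passed without either DOCA-EVs replicate. The fit without both arrays with weak hybridisation controls, chosen after seeing the data, leaves 1 DOCA array, so its count is not given.

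**Figure D1:**
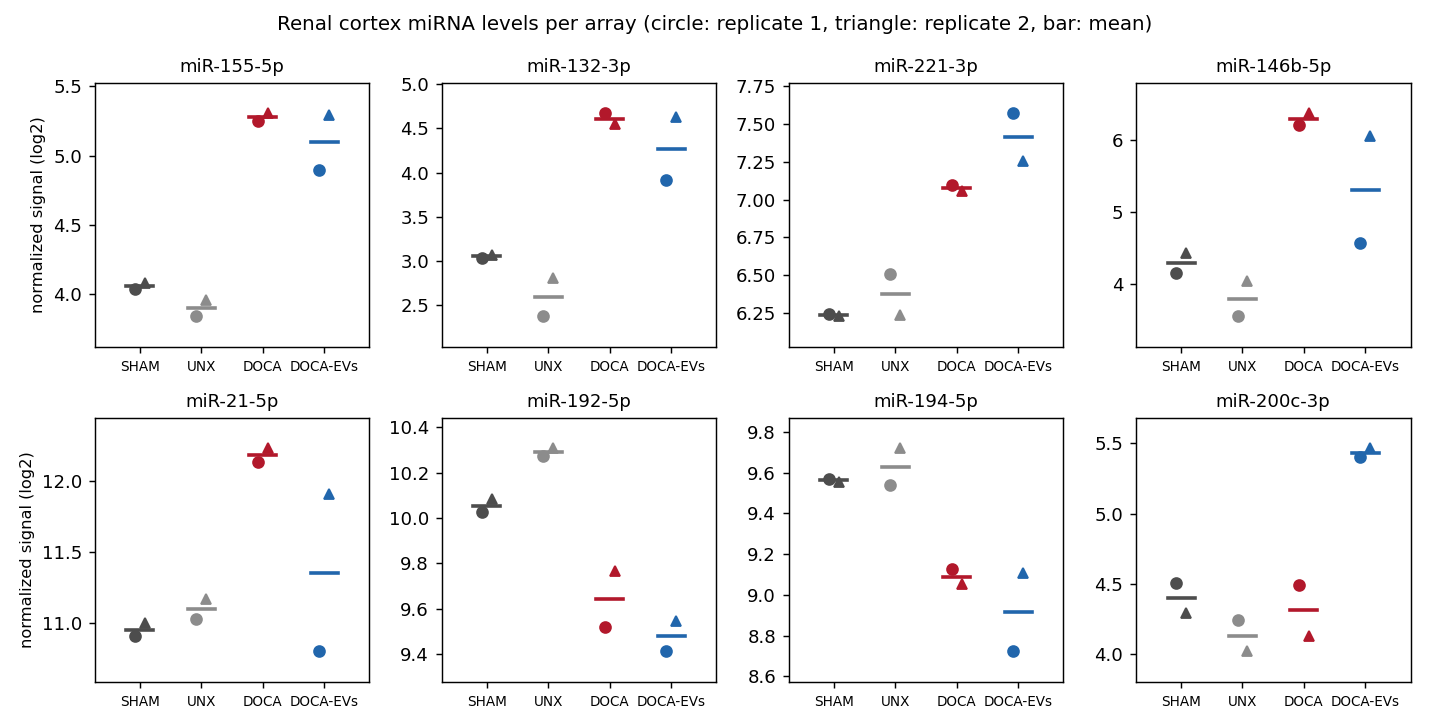
Log2 normalized signal of 8 miRNAs on each array by group, with circles for replicate 1, triangles for replicate 2 and a bar for the mean of 2 arrays. miR-155-5p lies at 5.28 in DOCA and 3.90 in UNX, and the DOCA-EVs arrays differ for miR-21-5p, at 10.80 and 11.91.

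Among the fixed lists, 6 of 14 passed in DOCA against UNX. The fibrosis-associated list rose: all 9 measured members had positive values, 1 (miR-132-3p) passed over all miRNAs and 4 passed adjusted over the list alone. Its median log2 fold change was 0.64, or 0.59 with the 2 members known only as bounds set to them, which lay 0.56 above the median of all miRNAs (0.20 to 0.57 over the scalings). Without UNX replicate 2 or DOCA replicate 1 the median was 0.95 or 1.02 (1.00 or 0.99 above that of all miRNAs), and 0.44 without both weakly hybridised arrays (0.34 above). Its camera adjusted p was 0.00075, and adjusted p = 0.37 with an estimated correlation. The leukocyte list rose, with 7 of 7 members positive, 1 past the threshold and 5 past adjusted over the list alone. miR-155-5p passed, and miR-223-3p of myeloid cells (0.89 ± 0.21) and miR-142-3p of blood cells (0.96 ± 0.27) did not pass over all miRNAs. That list lay 0.81 above the median of all miRNAs (0.19 to 0.81 over the scalings, 0.54 without DOCA replicate 2) with camera adjusted p = 0.0013, and adjusted p = 0.37 with an estimated correlation. The erythrocyte miRNA miR-451-5p was 8.59 and 6.74 on the DOCA replicates and 8.25 and 7.79 on the UNX replicates. The kidney tubule-enriched list fell: 7 of 8 members had negative values, 0 passed over all miRNAs and 5 passed adjusted over the list alone, with a median of −0.44, or −0.30 with bounds. It lay at −0.52 relative to the median of all miRNAs (−0.52 to −0.20), with camera adjusted p = 0.00075, and adjusted p = 0.37 with an estimated correlation.

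The other lists that fell in DOCA against UNX were the miR-30, miR-29 and miR-200 families. In the miR-30 family, abundant in podocytes and tubules, 8 of 10 members had negative values and 1 passed adjusted over the list alone, with miR-30c-5p at −0.43 ± 0.14 and a camera adjusted p of 0.0083. All 4 members of the miR-29 family, repressors of collagen genes, had negative values, with miR-29c-3p at −0.45 ± 0.13 past the threshold adjusted over the list alone and a camera adjusted p of 0.032. In the miR-200 family, which represses ZEB1 and ZEB2 in epithelium, 5 of 6 members had negative values and 0 passed, with miR-200b-3p at −0.40 ± 0.12, miR-429 at −0.37 ± 0.15 and a camera adjusted p of 0.032. With an estimated correlation the adjusted p was 0.37, 0.37 and 0.61 for the 3 families. Relative to the median of all miRNAs these families lay at −0.36, −0.30 and −0.41, negative in all 6 scalings, and the miR-30 family at −0.23 without UNX replicate 2. All 6 lists kept their side in both slide rows and passed with the replicate block. The miR-30 call was lost with all probes in the scaling (adjusted p = 0.050, just above the threshold). The miR-29 call was lost without UNX replicate 2 (adjusted p = 0.17, at −0.16 relative to all miRNAs) or DOCA replicate 1 (0.20), with all probes in the scaling (0.11), quantile normalization (0.053) or no scaling (0.074). The miR-200 call was lost without UNX replicate 1 (0.052), DOCA replicate 2 (0.17, with a median of −0.19 instead of −0.33) or both weakly hybridised arrays (0.16), and with 5 processing alternatives (0.058 to 0.18).

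DOCA-EVs against DOCA addresses the effect of the vesicles in DOCA-salt rats. No miRNA passed the threshold. The smallest adjusted p, 0.069, belonged to miR-200c-3p of epithelium, at 5.43 ± 0.04 in DOCA-EVs and 4.31 ± 0.26 in DOCA (log2 fold change 1.12 ± 0.18), to the hypoxia-induced miR-210-3p, at 6.33 ± 0.11 and 5.55 ± 0.09 (0.78 ± 0.13), to miR-31a-5p, measured at least 2.28-fold higher, and to miR-375-3p, not above background in either group. miR-326-3p was measured at least 1.36-fold higher (adjusted p = 0.097), and miR-9a-5p was not above background in either group. Negative values belonged to miR-188-5p (−0.64 ± 0.14, adjusted p = 0.15), miR-6216 (−1.10 ± 0.27, 0.19), miR-296-5p (−0.60 ± 0.15, 0.19), miR-494-3p (−0.63 ± 0.18, 0.27) and miR-211-3p (−0.51 ± 0.16, 0.32), and miR-3085 was below background in both. miR-21-5p was 11.36 ± 0.79 in DOCA-EVs, at 10.80 and 11.91 on the 2 arrays (−0.83 ± 0.34, adjusted p = 0.47). limma gave 25 of 242 miRNAs at an unadjusted p under 0.05, 10 higher and 15 lower, where chance gives 12.1, and the replicate block gave 0 past the threshold. Calls appeared under 3 other scalings (3, 4 and 3 miRNAs, all higher in DOCA-EVs). With DOCA-EVs replicate 2 left out, 1 array stands for that group, so its calls are not counted here. The fit without both weakly hybridised arrays, chosen after seeing the data, sets 1 DOCA-EVs array against 1 DOCA array. It holds no spread within either group. Its values were −1.37 for miR-21-5p, −1.39 for miR-142-3p and −1.61 for miR-451-5p, whose 2 DOCA replicates lay far apart.

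The miR-200 family rose in DOCA-EVs against DOCA. All 6 measured members had positive values, 0 passed over all miRNAs and 3 passed adjusted over the list alone, among them miR-200b-3p at 0.39 ± 0.12 and miR-200c-3p. The family lay 0.47 above the median of all miRNAs (0.22 to 0.48 over the scalings), or at a median of 0.41 with 1 member at its bound, with camera adjusted p = 0.00025, and adjusted p = 0.63 with an estimated correlation. It lay 0.12 and 0.56 above that median in slide rows 1 and 2. Its median log2 fold change was 0.47 with all arrays and 0.19 without DOCA replicate 2 (adjusted p = 0.030). The call was lost without DOCA-EVs replicate 2 (a median of 0.34, adjusted p = 0.091) and without both weakly hybridised arrays (0.22, 0.45). The leukocyte list fell, with 6 of 7 members negative and 0 past the threshold: miR-142-3p was at −0.77 ± 0.27, miR-146b-5p at −0.98 ± 0.47 and miR-223-3p at −0.43 ± 0.21. It lay at −0.22 relative to the median of all miRNAs (−0.23 to −0.09), −0.35 and −0.17 in slide rows 1 and 2, with camera adjusted p = 0.043, and adjusted p = 0.69 with an estimated correlation. The mean level of its members was 6.33 and 6.84 on the DOCA-EVs replicates and 6.91 and 7.03 on the DOCA replicates; miR-451-5p of erythrocytes was 7.02 and 7.09 against 8.59 and 6.74. The leukocyte call was lost under all 5 other scalings (adjusted p = 0.064 to 0.17) and without DOCA-EVs replicate 1 (0.51), DOCA replicate 2 (0.30), UNX replicate 1 (0.053) or UNX replicate 2 (0.055). Its median of −0.22 was −0.44 without DOCA-EVs replicate 2, −0.39 without DOCA replicate 1 and −0.39 without both weakly hybridised arrays, and relative to all miRNAs it lay at −0.14 without DOCA replicate 2. All 9 fibrosis-associated members had negative values, with a median of −0.24 and camera adjusted p = 0.12. The mesenchymal stromal EV cargo, miRNAs abundant in vesicles of such cells, had 9 positive and 8 negative values and a median of 0.00 (camera adjusted p = 0.35).

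**Figure D2:**
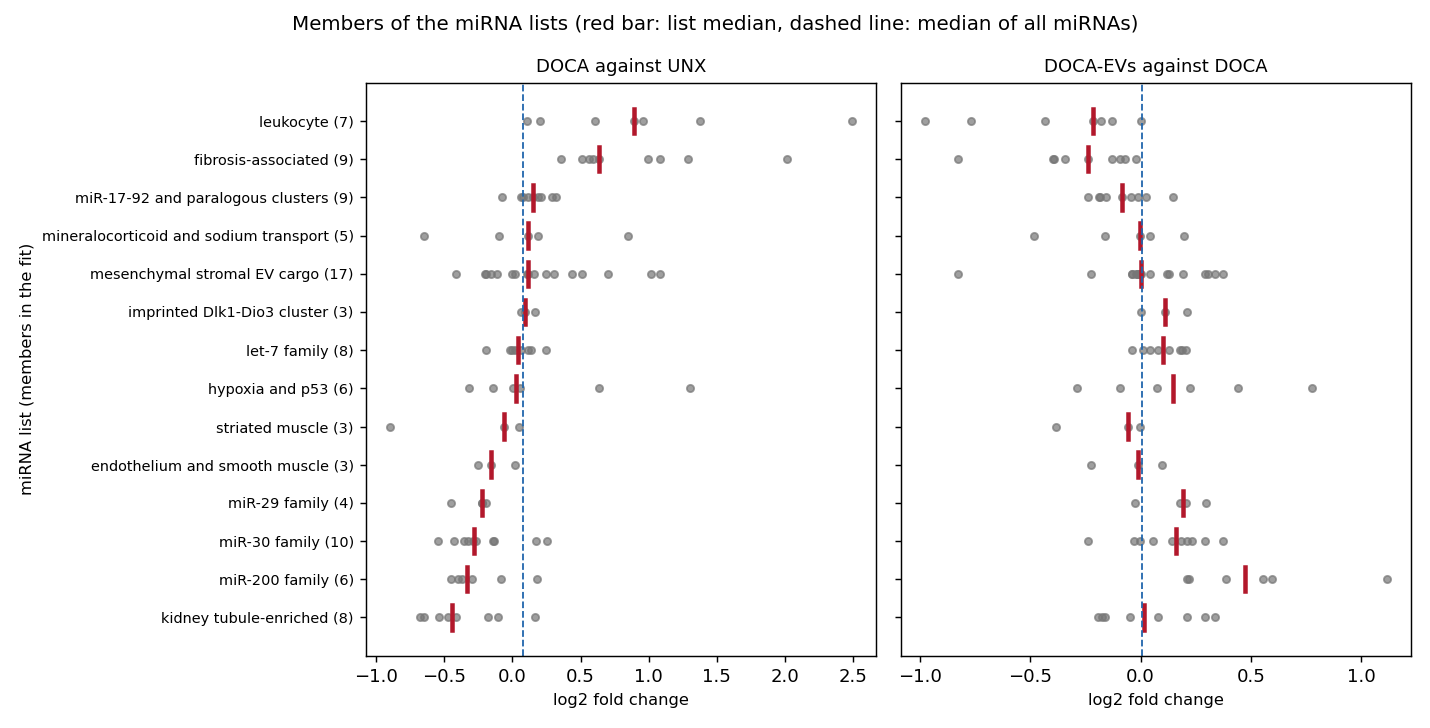
Log2 fold changes of the members of the 14 tested lists in DOCA against UNX and in DOCA-EVs against DOCA, each point 1 miRNA, with a red bar for the list median and a dashed line for the median of all 242 miRNAs. The leukocyte list has a median of 0.89 in the first comparison and −0.22 in the second, and the miR-200 family −0.33 and 0.47.

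Whether the vesicles moved miRNAs back was read from the fold changes of both comparisons across the 242 miRNAs, which are not independent replicates. Their correlation was −0.66, and −0.55 and −0.65 within slide rows 1 and 2. Both comparisons share the DOCA arrays, and 192 draws without an effect gave a median correlation of −0.61 (95% from −0.91 to 0.44), so the observed value lies inside that range. With each comparison on its own DOCA array the correlation was −0.47 and −0.13.

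DOCA against SHAM contrasts the DOCA rats with the sham control, and 2 of 242 miRNAs passed. miR-155-5p rose at least 1.97-fold (adjusted p = 0.031) and miR-375-3p was measured at least 1.01-fold lower (adjusted p = 0.0079). miR-375-3p was above background on no DOCA array and not on every SHAM array, so its p rests on values near the floor. Both passed with the replicate block. miR-155-5p lay higher in DOCA in both slide rows, but it was above background on no SHAM array, so its row values are not given. miR-142-3p was 6.96 ± 0.35 in DOCA and 5.53 ± 0.09 in SHAM (1.42 ± 0.27, adjusted p = 0.062), and miR-21-5p had a value of 1.23 ± 0.34 (0.15). No miRNA passed without either replicate of SHAM or DOCA, 1 passed without either UNX replicate, and 13 and 11 passed without DOCA-EVs replicates 1 and 2. The split of 1 higher and 1 lower was 7 and 1 with all probes in the scaling, 1 and 3 with the median of detected probes, 0 and 1 with quantile normalization or no scaling, and 0 and 0 with normexp and quantile normalization. Over the scalings the values ran from 0.17 to 1.42 for miR-155-5p and −2.11 to −0.18 for miR-375-3p.

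DOCA-EVs against UNX contrasts vesicle-treated rats with nephrectomy alone, and 6 miRNAs passed. miR-200c-3p rose at least 2.35-fold (log2 fold change 1.30 ± 0.18, adjusted p = 0.034) and miR-155-5p at least 1.90-fold (1.20 ± 0.16, 0.034), each above background on 1 of the 2 UNX arrays, and miR-221-3p rose 2.06-fold (1.04 ± 0.16, 0.038). miR-132-3p rose at least 1.07-fold (0.038) and miR-222-3p, of the same cluster as miR-221-3p, at least 1.88-fold (0.040). miR-192-5p, enriched in tubules, fell from 10.29 ± 0.02 to 9.48 ± 0.10 (−0.81 ± 0.14, 0.040). With the replicate block 7 passed: miR-222-3p was lost (adjusted p = 0.056), and miR-31a-5p (0.034) and miR-99b-3p (0.046), the latter named after its values were seen, were added. Over the scalings the values ran from 0.15 to 1.30 for miR-200c-3p, 0.13 to 1.20 for miR-155-5p, 0.40 to 1.04 for miR-221-3p, 0.14 to 1.68 for miR-132-3p, 0.12 to 1.39 for miR-222-3p and −0.95 to −0.68 for miR-192-5p. The slide rows gave −0.86 and −0.76 for miR-192-5p and 1.16 and 1.44 for miR-200c-3p. Leaving out any array of SHAM or DOCA, which keeps 2 arrays in each compared group, gave 0 calls. With an array of UNX or DOCA-EVs left out, 1 array stands for that group, so the calls are not counted here. The split of 5 higher and 1 lower was 0 and 0 with all probes in the scaling, quantile normalization or no scaling, 0 and 1 with normexp and quantile normalization, and 3 and 1 with the median of detected probes. The standard errors share the spread of all groups, whose median replicate difference was 0.06 log2 in SHAM and 0.37 in DOCA-EVs. With only the compared groups in the fit, or with array weights, 0 passed.

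DOCA-EVs against SHAM gave 0 miRNAs past the threshold in limma, with a smallest adjusted p of 0.057 and 32 miRNAs at an unadjusted p under 0.05 (17 higher and 15 lower). With the replicate block 5 passed in limma at an adjusted p of 0.028. miR-155-5p, miR-200c-3p, miR-221-3p (1.18 ± 0.14) and miR-31a-5p (1.23 ± 0.16) were higher in DOCA-EVs and miR-494-3p was lower (−0.94 ± 0.12). These 5 were named after their values were seen. miR-155-5p and miR-200c-3p were above background on no SHAM array, so no exact fold is given for them. Without DOCA-EVs replicate 1 that group is 1 array with no spread of its own, so the calls are not counted here.

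The pooled comparison set the 4 DOCA-salt arrays of DOCA and DOCA-EVs against the 4 standard-diet arrays of SHAM and UNX, and 16 miRNAs passed. SHAM rats were not nephrectomised and DOCA-EVs rats received vesicles, so this contrast also differs in nephrectomy and vesicles and does not isolate DOCA-salt. miR-155-5p rose at least 1.93-fold, to 5.19 ± 0.19 from 3.98 ± 0.11 (SD, n = 4; log2 fold change 1.21 ± 0.12, limma adjusted p = 0.0088), being above background on 1 of the 4 standard-diet arrays. miR-221-3p, which acts on KIT and on cell cycle inhibitors, rose 1.92-fold (0.94 ± 0.11, 0.0096), its cluster partner miR-222-3p at least 1.57-fold (0.012), and miR-34a-5p 1.55-fold (0.63 ± 0.08, 0.011). miR-132-3p rose at least 1.15-fold (0.0096). miR-192-5p fell from 10.17 ± 0.14 to 9.56 ± 0.15 (−0.61 ± 0.10, 0.024), miR-194-5p, of a shared cluster, fell from 9.60 ± 0.08 to 9.00 ± 0.19 (−0.59 ± 0.12, 0.042), and miR-192-3p fell at least 1.25-fold (0.041). miR-30e-3p fell by 0.41 log2 (SE 0.09, 0.050), and miR-375-3p was lower (0.0096) without a fold, being above background on 1 of 8 arrays. As members of the lists, miR-146b-5p rose at least 2.91-fold (0.041), miR-21-3p at least 1.76-fold (0.81 ± 0.17, 0.048) and miR-200c-3p at least 1.44-fold (0.61 ± 0.12, 0.047), the last 2 above background on 1 of the 4 standard-diet arrays. miR-188-5p (at least 1.47-fold, 0.041), miR-1949 (0.72 ± 0.15, 0.050) and miR-3584-5p (8.96-fold, 3.16 ± 0.61, 0.042) rose as well and were named after their values were seen.

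All 16 lay on the same side in both slide rows, with −0.69 and −0.54 for miR-192-5p. The rows gave 1.13 and 1.28 for miR-155-5p, which was above background on 1 of the 4 standard-diet arrays. Over the scalings the pooled values ran from 0.15 to 1.25 for miR-155-5p, 0.35 to 0.98 for miR-221-3p, 0.26 to 0.67 for miR-34a-5p, 2.07 to 3.20 for miR-3584-5p and 0.33 to 0.76 for miR-1949. For miRNAs given as bounds they ran from 0.30 to 1.80 for miR-146b-5p, 0.15 to 1.64 for miR-132-3p and 0.11 to 1.26 for miR-222-3p. They ran from 0.09 to 0.86 for miR-21-3p, 0.09 to 0.65 for miR-200c-3p and 0.08 to 0.59 for miR-188-5p. The bounds hold for the main scaling and not for normexp with quantile normalization, which gave the lowest of these values. Its offset draws dim signals together, so these ranges do not reflect the scaling between arrays alone. Among the 5 lower miRNAs the pooled values ran from −0.81 to −0.51 for miR-192-5p, −0.79 to −0.52 for miR-194-5p, −0.60 to −0.19 for miR-30e-3p and −0.83 to −0.07 for miR-192-3p. No range is given for miR-375-3p, which has no fold. The replicate block gave 18 calls: miR-15b-5p (adjusted p = 0.040), miR-223-3p (0.040) and miR-652-3p (0.048) were added and miR-21-3p was lost (0.051); miR-15b-5p and miR-652-3p were named after their values were seen. The count was 0 without either SHAM replicate, 4 without UNX replicate 1, 2 without UNX replicate 2, 9 without DOCA replicate 2 and 26 without DOCA-EVs replicate 1. The split of 11 higher and 5 lower was 7 and 11 with the median of detected probes, 7 and 4 with quantile normalization, 4 and 2 with no scaling, 2 and 4 with normexp and quantile normalization, and 6 and 1 with all probes in the scaling.

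Of the lists, 4 passed in the pooled comparison. The fibrosis-associated list rose, with all 9 values positive and 3 members past the threshold, miR-132-3p, miR-34a-5p and miR-21-3p, 4 adjusted over the list alone, a median of 0.63 (0.54 with bounds) and camera adjusted p = 0.00050. miR-21-5p was 11.77 ± 0.66 against 11.03 ± 0.11 (SD, n = 4; 0.74 ± 0.24, limma adjusted p = 0.13). The leukocyte list rose, with 7 of 7 positive, 2 past the threshold, miR-155-5p and miR-146b-5p, 6 adjusted over the list alone, a median of 0.59 and camera adjusted p = 0.00053. miR-142-3p had a value of 0.81 ± 0.19 (0.064) and miR-223-3p 0.59 ± 0.15 (0.076). The tubule-enriched list fell, with 7 of 8 negative, 3 past the threshold, miR-192-5p, miR-192-3p and miR-194-5p, and 3 adjusted over the list alone, a median of −0.23 and camera adjusted p = 0.0014. The miR-30 family fell, with 8 of 10 negative, 1 past the threshold, miR-30e-3p, and 1 adjusted over the list alone, a median of −0.20 and camera adjusted p = 0.012. With an estimated correlation the adjusted p was 0.38 for each of these 4 lists. Relative to the median of all miRNAs they lay at 0.64, 0.60, −0.22 and −0.19, on the same side in all 6 scalings and in both slide rows. Without both weakly hybridised arrays the median was 0.31 for the fibrosis-associated list (adjusted p = 0.037) and 0.36 for the leukocyte list (0.012). The fibrosis-associated median was 0.42 without DOCA-EVs replicate 2, or 0.35 above that of all miRNAs. The tubule-enriched median was −0.35 without UNX replicate 1 and −0.37 without UNX replicate 2, and the list lay at −0.14 relative to all miRNAs without DOCA-EVs replicate 1. The miR-30 family, also relative to all miRNAs, lay at −0.11 without UNX replicate 2, −0.10 without DOCA-EVs replicate 1, −0.33 without DOCA-EVs replicate 2 and −0.34 without both weakly hybridised arrays. The replicate block added striated muscle miRNAs, lower, and the mesenchymal stromal EV cargo, higher (adjusted p = 0.043 for both). The miR-30 call was lost without UNX replicate 2 (0.058) or DOCA-EVs replicate 1 (0.12) and with all probes in the scaling (0.069).

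The lists of endothelium and smooth muscle, striated muscle and EV cargo did not pass camera in the pooled comparison without the replicate block. All 3 endothelium and smooth muscle members had negative values, miR-143-3p −0.30 ± 0.11, miR-145-5p −0.22 ± 0.10 and miR-126a-3p −0.13 ± 0.11, with camera adjusted p = 0.076. The 3 striated muscle members had a median of −0.40 (0.076) and the 17 EV cargo members one of 0.14 (0.069), among which miR-221-3p and miR-222-3p passed. The erythrocyte list, with miR-451-5p at −0.69 ± 0.39 and miR-486 not above background, and the list of liver, nerve and endocrine miRNAs, with miR-375-3p, which passed as a single miRNA, and miR-9a-5p, had 2 measured members each and were not tested. Camera adjusted p was 0.12 for the miR-29 family, 0.83 for the miR-200 family, 0.12 for the let-7 family, 0.12 for the miR-17 cluster and its paralogues, 1.00 for mineralocorticoid and sodium transport, 0.32 for hypoxia and p53 and 0.51 for the imprinted Dlk1-Dio3 cluster. In DOCA against UNX the lists that did not pass had camera adjusted p from 0.42, for endothelium and smooth muscle at a median of −0.15, to 0.96. In DOCA-EVs against DOCA they ranged from 0.12 to 0.70.

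Of the 6 miRNAs followed whatever their p, miR-21-5p was 10.95 ± 0.06 in SHAM, 11.10 ± 0.10 in UNX, 12.19 ± 0.07 in DOCA and 11.36 ± 0.79 in DOCA-EVs. miR-192-5p was 10.05 ± 0.04, 10.29 ± 0.02, 9.64 ± 0.18 and 9.48 ± 0.10 in the same order, and miR-200b-3p was 10.10 ± 0.01, 10.34 ± 0.00, 9.93 ± 0.11 and 10.32 ± 0.07. miR-29b-3p was 11.62 ± 0.06, 11.91 ± 0.15, 11.69 ± 0.04 and 11.66 ± 0.29. miR-142-3p was 5.53 ± 0.09, 6.0 ± 0.10, 6.96 ± 0.35 and 6.19 ± 0.48. miR-451-5p was 8.07 ± 0.05, 8.02 ± 0.32, 7.66 ± 1.31 and 7.05 ± 0.05, with a spread between the DOCA replicates larger than any difference between group means.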

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

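The tests of an exchange of 2 arrays and of a lower share of tubule cells were chosen after the results were seen. The fit without the 2 weakly hybridised arrays was also chosen after seeing the data. The other tests in this part were set before.

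In scaled signal, hur_1, hur_2, hur_4 and hur_6 control spots were 1.19, 1.21, 1.28 and 1.26-fold higher on the 4 DOCA-salt arrays than on the 4 standard-diet arrays. Others were lower, such as dmr_3 at 0.83-fold. Control spots named mr_1, outside the measured miRNAs, were 1.64-fold higher. They alone were also separated in unscaled signal, with 1595 to 1780 against 1156 to 1222. Their target is not stated in the files, 15 kinds of control were looked at, and no explanation was tested.

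The pooled comparison of DOCA-salt with standard diet gave 16 miRNAs past the threshold with 4 group means and 13 with 1 mean per arm. Of the 35 splits of the 8 arrays into 4 and 4, 2 gave at least 13, so chance cannot be excluded by this count. The other splits with calls (36, 2 and 1) each set unequal numbers of arrays of the slide rows in an arm. All other splits with equal numbers gave 0, a reading made after the counts were seen. The highest other split gave 36, setting SHAM replicates 1 and 2, UNX replicate 1 and DOCA-EVs replicate 1 against the rest, and 1 of its 36 is among the 16, which points to a structure of the samples; 31 of the 36 were lower in the arm with DOCA replicate 1, 19 were detected on all 8 arrays, and whether signal, scaling or the tissue separates this split was not tested. For the 16 miRNAs, taking out the part of each fold change that follows the slide-row difference left a median share of 0.943. Leaving out the 2 arrays with weak hybridisation controls kept 0.932. Passing the threshold favours miRNAs whose replicates agree, and the replicates are the slide rows. Both shares are therefore high in part by selection. They decide neither whether the changes follow the axis of the row difference nor whether they follow the weak hybridisation. Each group has 1 array per row, so a row effect alike in all groups cancels in the fold changes. With the replicate block the value of miR-155-5p stayed at 1.21. Over all miRNAs in the fit the row difference correlated with the pooled fold changes at 0.489. An exchange of UNX replicate 2 and DOCA-EVs replicate 1 may also be weighed, and it cannot be told apart from spread within the groups: of 39 miRNAs past the threshold on the 6 other arrays, DOCA-EVs replicate 1 lay nearer the DOCA-salt mean for 13 (share 0.333) and UNX replicate 2 nearer the standard-diet mean for 23, while mr_1, at 1222 on UNX replicate 2 and 1623 on DOCA-EVs replicate 1, and miR-155-5p, at 3.96 and 4.90 there, followed the labels but were picked for following them. DOCA-salt, nephrectomy, the vesicles and the slide column, which follows the group, stay open and were not tested.

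The leukocyte list rose in the pooled comparison, with a median of 0.59 over 7 members, 0.36 without the 2 weakly hybridised arrays, and an adjusted p of 0.38 with an estimated correlation. A lower share of tubule cells was taken to raise every other cell type alike, but the 3 endothelium and smooth muscle members had a median of −0.22 and reached −0.13 at most. They lay below the leukocyte median by more than 0.13, the median of the standard errors of the single leukocyte members. This argues against a rise of every other cell type alike. The 3 vascular miRNAs do not stand for all other cell types, and the tubule-enriched list itself fell, with a median of −0.23. The check therefore does not decide whether a lower share of tubule cells contributed. Taking out the slide-row difference left a median share of 0.790 of the leukocyte changes, with a 25th percentile of 0.735. This argues against the axis of the row difference as the whole cause. A row effect alike in all groups cancels in these changes. Within slide rows 1 and 2 the list lay 0.41 and 0.75 above the median of all miRNAs. A lower share of tubule cells, more immune cells in the cortex and a higher level per cell stay open, and the arrays hold no cell counts to part them. Of the list's miRNAs, 1 (miR-146a-5p) is also in the EV cargo list; its level was 8.26 to 8.73 over the arrays.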

How the results depend on the processing

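The fits without the 2 weakly hybridised arrays and with outlier spots kept were chosen after seeing the data; all other alternatives were set before. Signal over background limits what can be compared: 516 miRNAs were not tested, and 7 of the 242 tested had no probe well above background on any array. No miRNA past the threshold changed its direction under an alternative, except that miR-375-3p in DOCA against UNX had a log2 fold change of 0 with a floor 4 times higher. Of the values of single miRNAs under alternatives, 419 of those past the threshold stayed past it and 353 did not; of the others, 6092 stayed below the threshold and kept their sign or moved by at most 1 SE, 127 passed it, and 177 changed sign by more than 1 SE. The block by slide was not run, since there is 1 slide. The causes of the changes below were not tested. Fits without an array have fewer samples, which cannot explain why counts rose without a DOCA-EVs replicate. All comparisons share the spread of all groups, whose median replicate difference was 0.06 log2 in SHAM and 0.37 in DOCA-EVs. The correlation of DOCA-EVs with DOCA fold changes stayed negative. The fibrosis-associated, leukocyte and tubule-enriched lists passed in DOCA against UNX and in the pooled comparison under every alternative run except the estimated correlation, with the pooled fibrosis median at 0.31 without the 2 weakly hybridised arrays against 0.63; the miR-30 call in DOCA against UNX was lost with all probes in the scaling (adjusted p = 0.050), and the leukocyte call in DOCA-EVs against DOCA also with the mean of log2 (0.053) and with miRNAs detected on all 8 arrays (0.093).

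Counts past the threshold were 0 for UNX against SHAM, 4 for DOCA against UNX, 0 for DOCA-EVs against DOCA, 2 for DOCA against SHAM, 6 for DOCA-EVs against UNX, 0 for DOCA-EVs against SHAM and 16 pooled. With quantile normalization they were 1 for DOCA against UNX, 3 for DOCA-EVs against DOCA, 1 for DOCA against SHAM, 0 for DOCA-EVs against UNX and 5 for DOCA-EVs against SHAM, with 0 lists in UNX against SHAM and 1 in DOCA-EVs against DOCA. The median over probes detected on all arrays gave 20 for DOCA against UNX, 4 for DOCA-EVs against DOCA and 4 for DOCA against SHAM. No scaling gave 0 for DOCA against UNX, 1 for DOCA against SHAM, 0 for DOCA-EVs against UNX and 6 pooled. The 75th percentile over all probes gave 8 for DOCA against SHAM, 0 for DOCA-EVs against UNX, 4 for DOCA-EVs against SHAM and 7 pooled. Under normexp and quantile normalization the counts were 10 for DOCA against UNX, 3 for DOCA-EVs against DOCA, 0 for DOCA against SHAM, 1 for DOCA-EVs against UNX, 5 for DOCA-EVs against SHAM and 6 pooled.

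The total gene signal of the scanner software gave 14 for DOCA against UNX and 3 for DOCA-EVs against SHAM, the mean of log2 over probes 1 for DOCA against SHAM, and the brightest probe 3 for DOCA-EVs against UNX. With no filter there were 2 for DOCA against UNX, 2 for DOCA-EVs against DOCA, 5 for DOCA against SHAM, 0 for DOCA-EVs against UNX and 3 pooled, with 2 lists in UNX against SHAM, 5 in DOCA-EVs against DOCA and 11 pooled. With miRNAs detected on all 8 arrays there were 6 for DOCA against SHAM, 3 for DOCA-EVs against UNX, 5 for DOCA-EVs against SHAM and 10 pooled. A floor 4 times lower gave 1 for DOCA-EVs against DOCA, and a floor 4 times higher 4 for DOCA-EVs against DOCA, 8 for DOCA-EVs against SHAM and 10 pooled. A variance trend gave 9 for DOCA against UNX and 1 for DOCA against SHAM. Array weights gave 3 for UNX against SHAM, 18 for DOCA against UNX, 18 for DOCA against SHAM, 0 for DOCA-EVs against UNX and 10 pooled. Fits of only the groups compared gave 7 for DOCA against UNX, 12 for DOCA against SHAM and 0 for DOCA-EVs against UNX. The replicate block gave 5 for DOCA-EVs against SHAM, where 0 had passed.

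Without the 2 weakly hybridised arrays DOCA and DOCA-EVs keep 1 array each, so counts for comparisons with 1 of these groups are not given. In UNX against SHAM 3 lists passed in that fit. With outlier spots kept there were 12 for DOCA against UNX, 11 for DOCA against SHAM and 3 for DOCA-EVs against SHAM, with 2 lists in UNX against SHAM. Estimated correlation in camera gave 0 lists in all 4 comparisons tested, and fry gave 0 in UNX against SHAM and 0 in DOCA-EVs against DOCA. With replicate 1 of DOCA in the first comparison and replicate 2 in the second, the correlation of fold changes was −0.471, and with the replicates the other way round −0.135.

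Leaving out each array in turn, with a lone array assumed to vary like the others, gave 0 to 13 for DOCA against UNX, 0 to 4 for DOCA-EVs against DOCA, 0 to 13 for DOCA against SHAM, 0 to 5 for DOCA-EVs against UNX, 0 to 7 for DOCA-EVs against SHAM and 0 to 26 pooled. The lists past the threshold were 0 to 2 in UNX against SHAM and 1 to 3 in DOCA-EVs against DOCA, and the correlation of fold changes (reversal by EVs) ran from −0.819 to −0.375. The highest counts came without DOCA-EVs replicate 1 in DOCA against UNX (13), DOCA against SHAM (13) and the pooled comparison (26). In the comparisons of DOCA-EVs with a single other group they came from fits that leave 1 array in DOCA-EVs. Without either SHAM replicate the counts of all 7 comparisons were 0, also of those that do not contain SHAM, which share its spread in the fit.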

Other observations

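The miRNAs named in this first paragraph were chosen after their values were seen; of the tests of the opposite fold changes, the one on separate DOCA arrays was set before the results were seen and the one of the slide rows on the covariance was chosen after. miR-3584-5p had the largest pooled log2 fold change of the 16 miRNAs past the threshold, and its replicates lay far apart in UNX and DOCA-EVs: 6.35 and 6.19 in SHAM, 5.96 and 8.11 in UNX, 10.67 and 10.71 in DOCA, and 10.003 and 7.88 in DOCA-EVs. miR-503-5p was 3.35 and 5.24 on the DOCA-EVs replicates, against 5.21 and 4.97 in DOCA and 3.25 and 3.40 in UNX, and miR-146b-5p was 4.56 and 6.05, against 6.21 and 6.37 in DOCA. Of pairs from shared clusters, in the pooled comparison miR-15b-5p was at 0.61 ± 0.15 and miR-16-5p at 0.06 ± 0.11, and miR-212-3p, partner of miR-132-3p, was at 0.48 ± 0.28, with adjusted p of 0.076, 0.79 and 0.37. The difference within a pair was not tested.

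The mean level of the fibrosis-associated members was 7.01 and 6.99 on the SHAM replicates, 6.79 and 6.96 in UNX, 7.64 and 7.89 in DOCA, and 7.17 and 7.80 in DOCA-EVs. For the tubule-enriched members it was 8.24 and 8.28 in SHAM, 8.28 and 8.38 in UNX, 7.95 and 7.99 in DOCA, and 7.94 and 8.09 in DOCA-EVs. The 2 erythrocyte members averaged 6.54 and 4.56 on the DOCA replicates and 6.10 and 6.07 in SHAM.

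Fold changes of DOCA-EVs against DOCA ran opposite to those of DOCA against UNX, with r = −0.66 across miRNAs. The row difference correlated with the 2 sets of fold changes at 0.375 and −0.302, and taking it out left a share of 0.829 of their covariance, or 0.737 with the row differences of all 4 groups taken out, which argues against the slide-row axis as the whole cause. Taking the row difference out on separate DOCA arrays decides nothing about the rows, since it enters both fold changes there with the same sign. It moved the correlations from −0.471 and −0.135 to −0.523 and −0.256. The shared DOCA arrays could account for it: on separate DOCA arrays the higher correlation was −0.135, below 0, but the covariance of −0.126 over all arrays lay inside the range of draws without an effect (−0.160 to 0.030). A return towards the level without DOCA-salt therefore cannot be told apart from the shared arrays with 2 arrays per group.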
